A study of Zea mays with 24 samples.

How the data were processed

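Endosperm of maize at 15 days after pollination was profiled in 24 libraries in 8 groups of 3: wild type and ZmICE1a mutant, wild type with and without IAA, and 4 groups of an experiment that combined genotype with JA. Per the labels' protocols each library came from 5 to 10 pooled endosperms, total RNA was extracted with a commercial plant kit and libraries were made by MP3RNA-seq, a method that reads the 3' ends of transcripts. The series also concerns CUT&Tag data, which are not analysed here.

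The deposited values are whole-number counts per feature, 1 file per library, for 46430 features that were the same in every file. Per the submitters' processing notes Trimmomatic 0.39 and HISAT2 2.2.1 were used. The counting program, the genome build, the annotation release, the use of strand and any removal of duplicate molecules are not given in the sources used here. The counts were used as deposited, and the files held no entry for unassigned reads. Genes that overlap on opposite strands, and near-identical copies such as those among the organelle open reading frames, are therefore uncertain.

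Samples were grouped by their titles. For 6 libraries of the JA experiment the title and the genotype field disagreed, and the names of their count files gave a further reading that equals exchanged titles. The results are given by title and with the 2 groups exchanged. The 8 comparisons, the tests, the alternatives, 24 gene lists and the rule for named genes were fixed before the data were examined.

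Features were classed by the form of their identifiers into 44146 nuclear gene models, 1765 ENSRNA features, 175 mitochondrial and 114 chloroplast protein-coding genes or open reading frames, 33 mitochondrial and 43 chloroplast ribosomal or transfer RNAs, and 154 microRNA precursors. A RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0 was used for names only. It named all organelle features and none of the nuclear gene models. All 24 lists therefore had 0 matched members and their tests are void. Feature classes, the respiratory chain and ATP synthase genes of the mitochondrion and the 50 features of highest mean CPM were taken as sets instead, after the data had been seen.

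Tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr at its minimum count of 10, quasi-likelihood fits and 2-sided tests, and a Benjamini-Hochberg adjusted p under 0.05. The genotype and IAA experiments were fitted alone with 6 libraries each, and the JA experiment as 12 libraries in 4 groups. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries. Median biological coefficients of variation were 0.092 in the genotype, 0.23 in the IAA and 0.15 in the JA experiment. Sets with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, adjusted over the sets of a comparison.

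The naming rule took features past the threshold with at least 10 CPM in 1 of the groups compared and with groups that did not overlap, ordered by log2 fold change, up to 8 in each direction for features with a name. The rule required a name, so for nuclear genes up to 2 identifiers in each direction were taken by the same order, a change made after the data had been seen. Where a named gene held 3 or fewer counts over a group, a ratio with an exact 95% binomial interval is given, and where it held 0, a bound at a floor of 3 counts over the group. Such intervals and bounds cover counting error only.

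The pipeline was tested on simulated data drawn from the real means, library sizes and fitted dispersions, with 100 genes changed at each fold size. For mutant against wild type 74% of 2-fold and 97% of 4-fold changes were recovered among 17534 genes, and 9.04% of calls were false. In the IAA comparison 27% and 75% were recovered among 7273 genes with 11.3% false calls, in titled wild type JA-treated against wild type JA-untreated 38% and 82% among 10834 genes with 6.98% false calls, and in the non-additive contrast 9% and 58% among 10891 genes with 6.94% false calls. The false share lay above the nominal 5% in all 4 simulations. The IAA libraries were thus far less able to show a 2-fold change than the genotype libraries. They were shallower and also more variable, with a median biological coefficient of variation of 0.23 against 0.092. The simulation did not separate depth from spread.

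Replicates were checked for duplicates by chi-square over features with at least 10 counts in a pair. The statistic per degree of freedom ran from 1.76 to 6.44 over 24 pairs within groups and from 3.29 to 51.3 over 252 pairs across groups, so that no library was a copy of another within sampling noise. The alternatives were DESeq2 1.42.0, RLE scaling, library sizes without the 50 most abundant features, no low-count filter, a filter of 10 CPM in 3 libraries, a minimum absolute log2 fold change of 1, the replicate number as a block, fits of the compared groups alone, exchanged labels and each library left out. Leaving out ENSRNA features, or these and organelle features, was added after the data had been seen.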

Results

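RNA from maize (Zea mays) endosperm, the nutritive tissue of the kernel, was counted by MP3RNA-seq at 15 days after pollination in 24 libraries, each made from 5 to 10 pooled endosperms. The libraries formed 8 groups of 3. A mutant of ZmICE1a, a maize relative of the bHLH transcription factor ICE1, was set against wild type in 1 experiment. Wild type with and without IAA (indole-3-acetic acid, the main natural auxin) made up another. The last experiment crossed genotype with JA (jasmonic acid, a hormone of wounding and defence responses) in 4 groups. Doses and times of the hormone treatments are not given in the sources used here. The labels do not say whether replicates came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

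Depth differed between the experiments. Total counts per library ran from 3109928 to 4875478 in the genotype experiment, from 432016 to 959735 in the IAA experiment and from 839322 to 1917363 in the JA experiment. Depth also separated groups within each experiment. In the genotype experiment wild type libraries held 4392280 counts or more and mutant ones 3943038 or fewer. Untreated IAA libraries held 609023 or more and treated ones 608544 or fewer. Wild type JA-untreated libraries held 1660718 or more and the other JA libraries 1353622 or fewer. An effect of depth was not separated from that of the group in comparisons of these groups. The number of features with at least 1 count ranged from 17361 to 27819. Nuclear gene models took most counts in every library. ENSRNA features, which the files list without a name, took 0.375% to 0.552% of the counts in the genotype experiment. Their share was 10.7% in replicate 1 and 6.84% in replicate 2 of the libraries titled wild type JA-treated, above the 1.13% to 3.61% of the other groups of that experiment, and 3.33% in replicate 3, within that range.

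**Figure D1:**
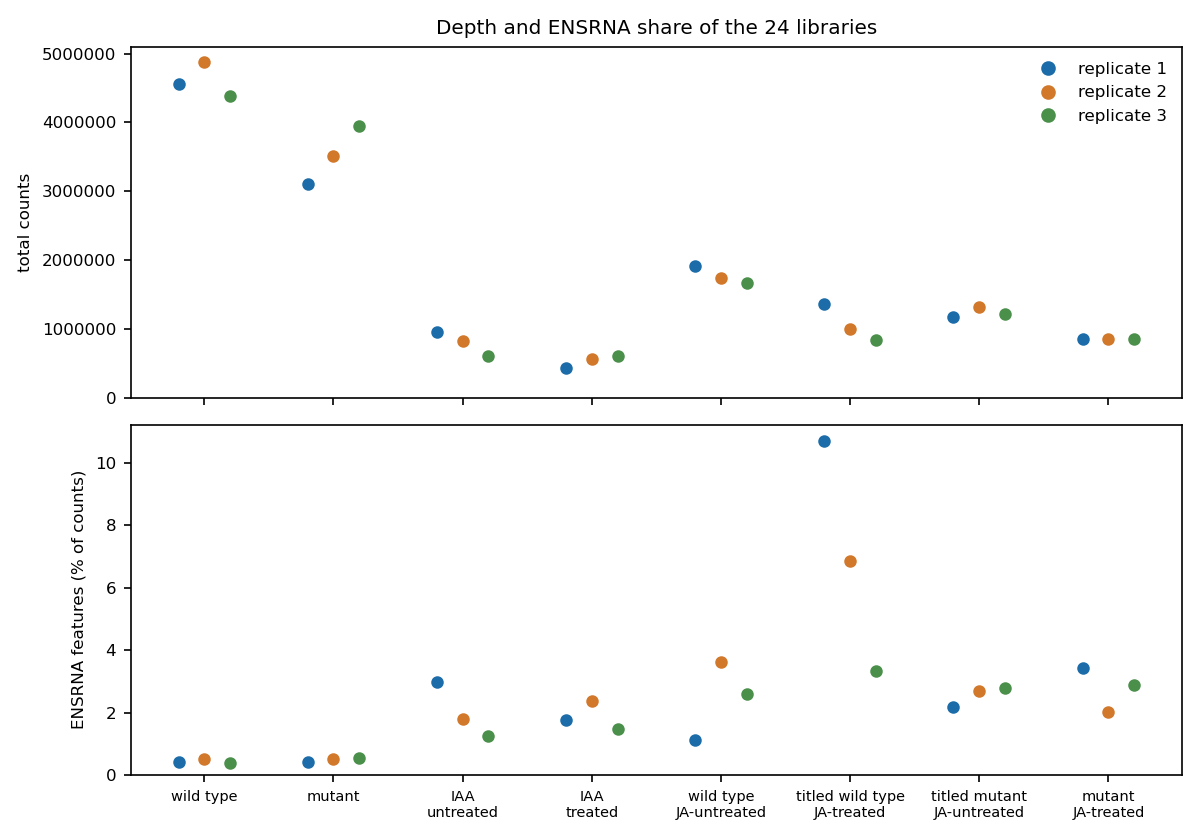
Total counts (upper plot) and the percentage of counts in ENSRNA features (lower plot) for each of the 24 libraries, 1 point per library, with colours marking replicate numbers. The genotype libraries hold 3109928 to 4875478 counts, and the highest ENSRNA share is 10.7%, in replicate 1 of the group titled wild type JA-treated.

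In the JA experiment 2 of the 4 groups carried labels that disagreed. The libraries titled wild type JA-treated had a genotype field reading mutant, and those titled mutant JA-untreated had a genotype field reading wild type. Their treatment fields followed the titles. The names given to the deposited counts hold a further reading, in which the former group is mutant without JA and the latter wild type with JA, as if the 2 titles were exchanged. On that reading the comparisons of this experiment given below as a JA response would be effects of genotype, and those given as effects of genotype would be JA responses. These 2 groups are called titled wild type JA-treated and titled mutant JA-untreated below, after their titles alone. All labels agreed for the other 2 groups, wild type JA-untreated and mutant JA-treated.

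The files do not pair the nuclear gene identifiers with names, and the reference table names none of the 44146 nuclear gene models. The level of ZmICE1a, which would have checked the genotype labels, is therefore not given, and none of the 24 gene lists fixed in advance had a named member. Names were given for the mitochondrial and chloroplast genes. For nuclear genes, up to 2 identifiers that rose and 2 that fell are given per comparison.

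The mutant was compared with wild type to find the genes that differ between them. In the mutant, 576 genes were higher and 528 were lower among 17841 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 3 libraries per group). Most of the changes were small, with a median absolute log2 fold change of 0.47, and 92 genes rose and 82 fell by at least 1 on the log2 scale. Nuclear gene Zm00001d020949 rose from 3.56 ± 1.35 CPM in wild type to 15.2 ± 4.5 in the mutant (SD, n = 3 each; log2 fold change 2.07 ± 0.27 SE, edgeR adjusted p = 4.55e-05). Zm00001d041436 rose from 3.36 ± 0.481 to 13.6 ± 1.89 CPM (2.00 ± 0.23, edgeR adjusted p = 6.86e-06). The nuclear gene Zm00001d041300 fell from 16.7 ± 1.74 to 2.81 ± 0.434 CPM (log2 fold change −2.55 ± 0.22, edgeR adjusted p = 2.42e-07), and Zm00001d040153 fell from 15.3 ± 3.97 to 3.59 ± 1.16 CPM (−2.10 ± 0.27, edgeR adjusted p = 2.93e-05). Zm00001d041436, Zm00001d041300 and Zm00001d040153 lie in a run of identifiers where calls were concentrated, described under other observations. Whether ZmICE1a or a genome segment that differs between the lines moved them is not settled.

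Transcripts of the organelle genomes did not pass the test over all genes in the mutant. Of 16 chloroplast ribosomal or transfer RNAs 15 had positive log2 fold changes, with a median of 0.61. Adjusted over that list alone, 7 were higher and 1 lower by edgeR. That set had camera adjusted p = 0.00064 with the preset correlation and 0.66 with an estimated correlation. Of 35 chloroplast protein-coding features 30 had positive log2 fold changes, with a median of 0.61, and 0 were called by edgeR or DESeq2, with 11 at an unadjusted p under 0.05 in edgeR. The set as a whole ranked higher in the mutant with the preset correlation (camera adjusted p = 4.3e-05), and adjusted p = 0.66 with an estimated correlation. Without wild type replicate 2, 28 of 43 were positive with a median of 0.38, and without mutant replicate 2, 41 of 45 with a median of 0.33, and 0 had an unadjusted p under 0.05 in either fit. Of 23 mitochondrial protein-coding features 18 were positive and 0 were called by either tool, with 5 at an unadjusted p under 0.05 in edgeR. Without mutant replicate 2 only 10 of 23 were positive (median −0.04, against 0.26 with all libraries), and without wild type replicate 1 or mutant replicate 1, 2 of 25 and 2 of 30 were called higher. Of 222 ENSRNA features tested 19 rose and 8 fell, and the called ones had a median absolute log2 fold change of 3.53, against 0.46 for the 1077 nuclear genes called. DESeq2 called 6 of them higher and 3 lower, and the number lower was 13 without wild type replicate 1 and 17 without wild type replicate 3.

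The count of changed genes was lower with DESeq2, which called 560, and 556 of these were among the edgeR calls. The 4 nuclear genes named kept their calls without any 1 of the 6 libraries. It fell to 702 without wild type replicate 1 and to 701 without mutant replicate 2.

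**Figure D2:**
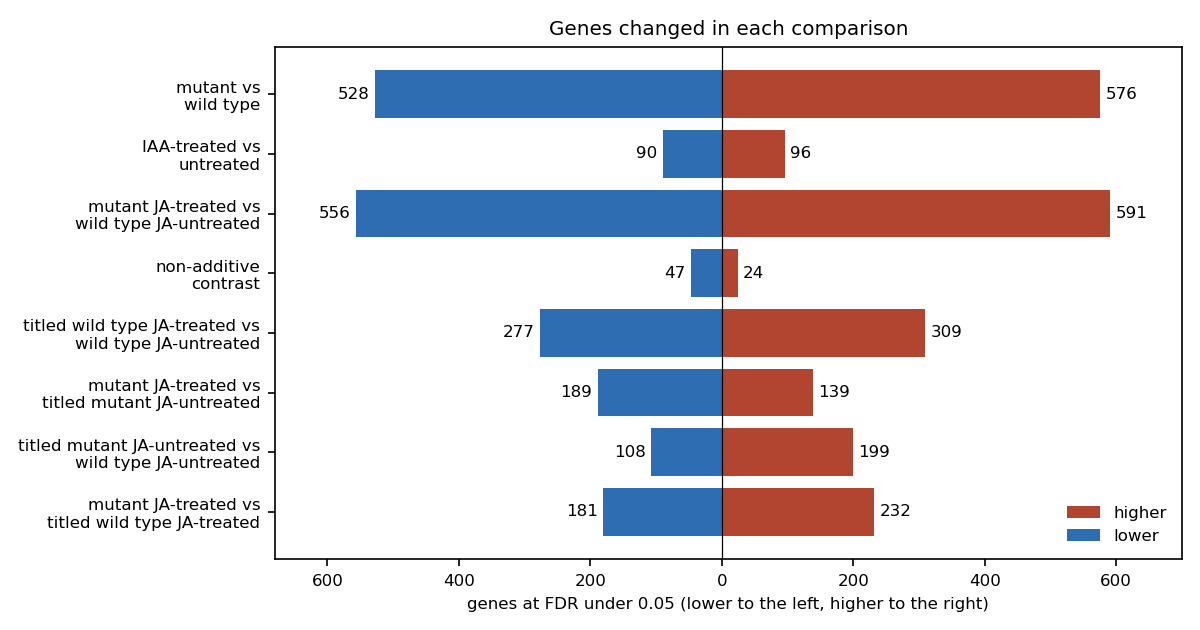
Number of genes at an adjusted p under 0.05 (edgeR) in each of the 8 comparisons, with higher genes to the right of 0 and lower genes to the left. The mutant differs from wild type in 576 higher and 528 lower genes, and IAA in 96 higher and 90 lower.

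IAA-treated wild type endosperm was compared with its own untreated control. After IAA 96 genes were higher and 90 were lower among 7687 tested, of which 48 rose and 26 fell by at least 1 on the log2 scale. The largest rise by the naming rule was that of Zm00001d049576, from 49.9 ± 15.1 CPM to 394 ± 17.8 (SD, n = 3 each; log2 fold change 2.96 ± 0.19 SE, edgeR adjusted p = 1.14e-06). Zm00001d003776 rose from 3.43 ± 1.7 to 28.4 ± 4.75 CPM (2.93 ± 0.59, edgeR adjusted p = 0.0181). Zm00001d035646 fell from 28.1 ± 2.19 to 1.28 ± 2.22 CPM (edgeR adjusted p = 0.0134), where the treated libraries held 2 counts in all, so that wild type without IAA was 20.7-fold higher with an exact 95% interval of 5.49 to 175 that covers counting error only. Zm00001d011640 fell from 26.3 ± 9.68 to 2.92 ± 2.59 CPM (−3.19 ± 0.74, edgeR adjusted p = 0.0383).

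The mitochondrial gene rps1, which encodes a protein of the mitochondrial ribosome, fell after IAA from 104 ± 4.69 to 50.5 ± 9.84 CPM (SD, n = 3 each; log2 fold change −1.05 ± 0.23 SE, edgeR adjusted p = 0.0288). Its call was lost with the replicate number as a block (edgeR adjusted p = 0.057). It was the 1 called among 10 mitochondrial protein-coding features tested, and 0 of 30 chloroplast ones were called by edgeR or DESeq2, with 1 at an unadjusted p under 0.05 in edgeR. Zm00001d049576 kept its call without any 1 of the 6 libraries. The calls of rps1, Zm00001d003776 and Zm00001d011640 were lost without each of the 6 in turn, with edgeR adjusted p up to 0.13, 0.1 and 0.27, and that of Zm00001d035646 in 4 of the 6 fits, without untreated replicates 2 and 3 and treated replicates 1 and 3, up to 0.082.

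These counts rest on shallow libraries. Without untreated replicate 2, untreated replicate 3 or treated replicates 1, 2 and 3 in turn, 82, 78, 109, 97 and 88 genes were called. Without untreated replicate 1, the deepest IAA library at 959735 counts, the number was 191, against 186 with all libraries. Leaving the low-count filter out gave 364 calls, 115 higher and 249 lower, and leaving ENSRNA features out of the counts gave 319.

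In the JA experiment the labels of the mutant JA-treated and wild type JA-untreated groups agreed, and these groups differ in both genotype and treatment. In mutant JA-treated endosperm 591 genes were higher and 556 lower among 11265 tested (edgeR, 12 libraries in 1 fit), and 462 of them changed by at least 1 on the log2 scale. Zm00001d034107 rose from 0.874 ± 0.779 to 19.2 ± 1.63 CPM (SD, n = 3 each; log2 fold change 4.25 ± 0.51 SE, edgeR adjusted p = 7.7e-05). Zm00001d006669 rose from 0.52 ± 0.499 to 14.5 ± 2.97 CPM (edgeR adjusted p = 0.000258), from 3 counts to 35, a ratio of 26.7 with an exact 95% interval of 8.41 to 136 for counting error. Zm00001d016674 fell from 30.9 ± 4.69 to 1.66 ± 1.88 CPM (−4.14 ± 0.59, edgeR adjusted p = 0.000326), and Zm00001d042140 from 16.6 ± 2.68 to 2.06 ± 1.89 CPM (−2.93 ± 0.59, edgeR adjusted p = 0.00473).

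In mutant JA-treated endosperm, of 26 mitochondrial protein-coding features, 10 were higher and 0 lower over all genes tested, 14 were higher when adjusted over the list alone, and all 26 had positive log2 fold changes with a median of 0.94. With each library left out, 8 to 10 of the 27 to 39 features then tested were higher and 0 lower, and the median ran from 0.51 without mutant JA-treated replicate 3 to 0.89. DESeq2 called 9 of the 26 higher. The set ranked above other genes (camera adjusted p = 3.6e-09 with the preset correlation), and adjusted p = 0.062 with an estimated correlation, so that this set call was lost. Among genes of the respiratory chain and ATP synthase 4 of 7 rose, and for this set too the camera call (adjusted p = 7.3e-05) was lost with an estimated correlation (adjusted p = 0.062). The 4 were cox1, a catalytic subunit of cytochrome c oxidase, at 14.1 ± 6.32 CPM in wild type JA-untreated and 42.5 ± 13 in mutant JA-treated (SD, n = 3 each; log2 fold change 1.59 ± 0.31 SE, edgeR adjusted p = 0.00397), cox3 of the same enzyme (1.38 ± 0.15), nad4 of complex I (1.21 ± 0.22) and atp4 of ATP synthase (1.16 ± 0.15). The ribosomal gene rps1 rose by 1.08 ± 0.19 and the small-subunit ribosomal RNA rrn18 by 1.13 ± 0.20 on the log2 scale. The open reading frames orf147-b (1.2 ± 0.17) and orf101-a (1.01 ± 0.15) rose too. All of these named genes kept their calls without any 1 of the 6 libraries. Organelle genes can share reads with copies elsewhere in the genome, and how the counting treated such reads is not given in the sources used here.

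**Figure D3:**
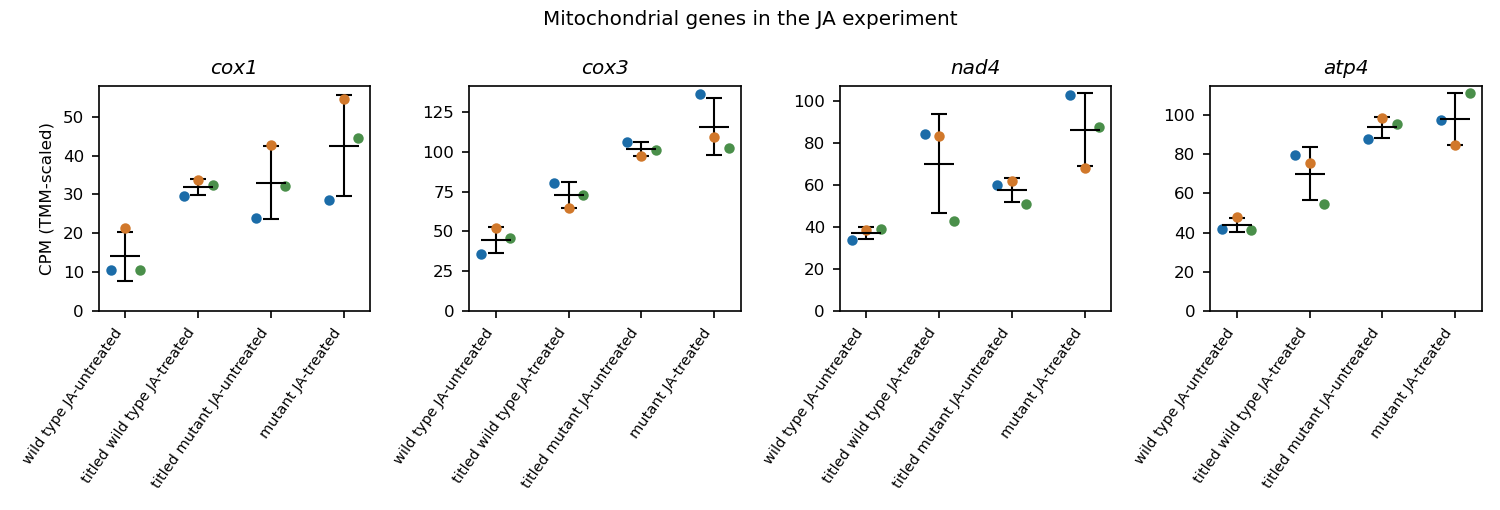
TMM-scaled CPM of the mitochondrial genes cox1, cox3, nad4 and atp4 in the 12 libraries of the JA experiment, with 1 point per library, colours for replicate numbers, and horizontal marks with bars for the mean and SD of each group of 3. Mean cox1 is 14.1 CPM in wild type JA-untreated and 42.5 CPM in mutant JA-treated.

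The most abundant transcripts also differed between these groups. Of the 50 features with the highest mean CPM, 26 were higher and 11 lower in mutant JA-treated endosperm, and the set ranked above other genes (camera adjusted p = 3.4e-08), with adjusted p = 0.038 with an estimated correlation. Without the low-count filter 542 genes were higher and 805 lower in this comparison.

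The group titled wild type JA-treated was compared with wild type JA-untreated, a contrast that by title gives the JA response of wild type. In the titled wild type JA-treated group 309 genes were higher and 277 lower, 228 of them by at least 1 on the log2 scale. Zm00001d020949, which rose in the mutant of the genotype experiment, rose here from 1.13 ± 1.49 to 12.7 ± 7.06 CPM (SD, n = 3 each; log2 fold change 3.36 ± 0.70 SE, edgeR adjusted p = 0.0109). Zm00001d020949 was at 1.73 ± 1.68 CPM in the titled mutant JA-untreated group and at 11.6 ± 0.607 in mutant JA-treated endosperm. Zm00001d034538 rose from 0.542 ± 0.565 to 12.3 ± 2.61 CPM (edgeR adjusted p = 0.000818), from 3 counts to 38, a ratio of 21.8 with an exact 95% interval of 6.93 to 111 for counting error. Zm00001d038913 was at 15.9 ± 3.13 CPM in wild type JA-untreated and at 0 counts in all 3 libraries titled wild type JA-treated, so that it was at least 17.0-fold lower there at a floor of 3 counts over the group. Zm00001d042140 fell from 16.6 ± 2.68 to 0.893 ± 0.794 CPM (edgeR adjusted p = 0.00205), from 91 counts to 3, a ratio of 17.6 with an interval of 5.83 to 86.9. The call of Zm00001d020949 was lost without wild type JA-untreated replicates 1 or 3 or titled wild type JA-treated replicate 3, with edgeR adjusted p up to 0.054, and the other 3 genes kept theirs without any 1 library.

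Mitochondrial genes were higher in the titled wild type JA-treated group for 4 of 26 protein-coding features, which were the respiratory chain and ATP synthase genes cox1 (1.17 ± 0.31), nad4 (0.93 ± 0.21), cox3 (0.71 ± 0.15) and atp4 (0.68 ± 0.15). The rise in mutant JA-treated endosperm used the same wild type JA-untreated libraries, so these rises are not independent. Mutant JA-treated endosperm had 0 of 26 higher against titled mutant JA-untreated and 2 against titled wild type JA-treated. The large-subunit ribosomal RNA rrn26 rose by 0.84 ± 0.15 on the log2 scale. Over the list alone 10 of the 26 were called, and the set had adjusted p = 2.4e-06 with the preset correlation and adjusted p = 0.13 with an estimated correlation. Without wild type JA-untreated replicate 1, or without titled wild type JA-treated replicate 1, 0 of the 39 features then tested were called by edgeR, with 9 at an unadjusted p under 0.05 in each fit. Without wild type JA-untreated replicate 3 or titled wild type JA-treated replicate 2 the number was 1, and 9 of 30 were called with ENSRNA features left out of the counts. ENSRNA features were higher for 37 of 238 and lower for 2 (camera adjusted p = 8.9e-15, and adjusted p = 0.081 with an estimated correlation), and higher for 22 without wild type JA-untreated replicate 1 and 20 without titled wild type JA-treated replicate 1. The count of 586 changed genes fell to 300, 359 and 350 without wild type JA-untreated replicates 1, 2 and 3, and to 363 without titled wild type JA-treated replicate 1. With the 2 groups of disagreeing labels exchanged, the same contrast gave 307 genes.

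The group titled mutant JA-untreated was compared with wild type JA-untreated, by title the effect of genotype without JA. In it 199 genes were higher and 108 lower. Zm00001d018819 rose from 0.967 ± 1.22 to 12.3 ± 5.54 CPM (SD, n = 3 each; log2 fold change 3.59 ± 0.69 SE, edgeR adjusted p = 0.00999), and Zm00001d008577 from 4.38 ± 1.12 to 27.9 ± 7.11 CPM (2.65 ± 0.28, edgeR adjusted p = 5.65e-05). Zm00001d045462 fell from 68.6 ± 13.4 to 18.5 ± 2.93 CPM (−1.88 ± 0.26, edgeR adjusted p = 0.000582) and Zm00001d016674 from 30.9 ± 4.69 to 8.9 ± 6.28 CPM (−1.80 ± 0.37, edgeR adjusted p = 0.0167). Mitochondrial features were higher for 5 of 26, with log2 fold changes of 1.35 ± 0.16 for orf147-b, 1.23 ± 0.31 for cox1, 1.19 ± 0.15 for cox3, 1.10 ± 0.15 for atp4 and 1.00 ± 0.19 for rps1. Without wild type JA-untreated replicate 1 the number was 3. These calls share their wild type JA-untreated libraries with the comparisons above and are not independent of them. The set had adjusted p = 6.3e-10 with the preset correlation and adjusted p = 0.058 with an estimated correlation. Of the 50 most abundant features 26 rose and 1 fell, and this set kept its call with an estimated correlation (camera adjusted p = 0.00035). These features took 46.4% ± 0.569 of all counts in the titled mutant JA-untreated libraries and 40.8% ± 0.874 in wild type JA-untreated (SD, n = 3 each).

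Of the 307 genes called in that comparison, the count fell to 164, 194 and 154 without wild type JA-untreated replicates 1, 2 and 3, and to 182, 167 and 171 without titled mutant JA-untreated replicates 1, 2 and 3. The calls of cox1, Zm00001d018819 and Zm00001d016674 were each lost in 4 of those 6 fits, with edgeR adjusted p up to 0.21, 0.058 and 0.095. The count was 475 without the low-count filter, 249 higher and 226 lower, and 586 with the 2 groups exchanged.

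Mutant JA-treated endosperm was also compared with each of the 2 groups of disagreeing labels. Against the group titled mutant JA-untreated, by title the JA response of the mutant, 139 genes were higher and 189 lower. Zm00001d042504 was at 8.7 ± 4.67 CPM in the titled mutant JA-untreated group and at 74.0 ± 7.85 in mutant JA-treated endosperm (SD, n = 3 each; log2 fold change 3.09 ± 0.29 SE, edgeR adjusted p = 2.69e-05). It was at 10.9 ± 3.45 CPM in wild type JA-untreated and at 66.2 ± 1.98 in the titled wild type JA-treated group, and it kept its call without any 1 library. Zm00001d039484 rose from 1.7 ± 2.2 to 15.0 ± 4.51 CPM (3.01 ± 0.66, edgeR adjusted p = 0.0208). Zm00001d008417 fell from 11 ± 4.83 to 2.07 ± 1.41 CPM (−2.34 ± 0.56, edgeR adjusted p = 0.0354) and Zm00001d042361 from 13.8 ± 1.15 to 2.9 ± 1.87 CPM (−2.21 ± 0.50, edgeR adjusted p = 0.027). The calls of these 3 genes were lost in 4, 6 and 5 of the 6 fits that left out 1 library, with edgeR adjusted p up to 0.094, 0.14 and 0.11. Of the 26 mitochondrial protein-coding features 0 were called by edgeR or DESeq2, with 4 at an unadjusted p under 0.05 in edgeR and a median log2 fold change of 0.27. Without mutant JA-treated replicate 2, 2 of 39 were called higher and the median was 0.66, and without replicate 1 the median was 0.08. The count of 328 fell to 181, 198 and 187 without titled mutant JA-untreated replicates 1, 2 and 3 and to 216, 180 and 209 without mutant JA-treated replicates 1, 2 and 3, and it was 214 in a fit of these 6 libraries alone.

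Against the group titled wild type JA-treated, by title the effect of genotype under JA, 232 genes were higher and 181 lower in mutant JA-treated endosperm. Zm00001d034107 was at 19.2 ± 1.63 CPM there and at 0.253 ± 0.438 in the titled wild type JA-treated group (SD, n = 3 each; edgeR adjusted p = 0.000245), 46 counts against 1, a ratio of 61.0 with an exact 95% interval of 10.4 to 2460 for counting error. Zm00001d031158 was at 16.6 ± 3.81 CPM in mutant JA-treated endosperm and at 1.27 ± 2.19 in the titled wild type JA-treated group (log2 fold change 3.34 ± 0.76 SE, edgeR adjusted p = 0.0225). Lower in mutant JA-treated endosperm were Zm00001d029716, at 8.3 ± 3.5 against 40.6 ± 4.9 CPM (−2.28 ± 0.38, edgeR adjusted p = 0.00264), and Zm00001d034538, at 2.48 ± 2.15 against 12.3 ± 2.61 CPM (−2.23 ± 0.56, edgeR adjusted p = 0.0408). Zm00001d034107 and Zm00001d029716 kept their calls without any 1 library, while those of Zm00001d031158 and Zm00001d034538 were lost in 4 and 6 of the 6 fits, with edgeR adjusted p up to 0.085 and 0.16. The mitochondrial orf147-b (0.71 ± 0.17) and cox3 (0.67 ± 0.15) were higher, with calls lost in 6 and 4 of the 6 fits that left out 1 library, at edgeR adjusted p up to 0.18 and 0.12. Of 238 ENSRNA features 16 were lower and 1 higher. The number lower was 9 without titled wild type JA-treated replicate 1, 3, 5 and 6 without mutant JA-treated replicates 1, 2 and 3, and 30 with DESeq2. The 50 most abundant features were higher for 21 and lower for 8 (camera adjusted p = 0.029 with an estimated correlation). The count of 413 fell to 247 without titled wild type JA-treated replicate 2, to 242 and 269 without mutant JA-treated replicates 2 and 3, and to 224 in a fit of the 6 libraries alone. With no low-count filter the balance turned, to 252 genes higher and 340 lower.

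The non-additive contrast asked whether genotype and JA act on a gene independently, and its value is the same when the 2 disagreeing groups are exchanged. It has this meaning only if those groups fill the 2 remaining cells of the design. With genotype as their genotype fields read, they would share the labels of the 2 other groups, and the contrast would not measure non-additivity. It passed for 71 of 11265 genes, 24 positive and 47 negative. Zm00001d006010 was at 62.4 ± 6.65 CPM in mutant JA-treated endosperm and at 18.2 ± 3.66, 21.3 ± 4.89 and 13.5 ± 7.09 CPM in wild type JA-untreated, titled wild type JA-treated and titled mutant JA-untreated (SD, n = 3 each; log2 contrast 1.99 ± 0.42 SE, edgeR adjusted p = 0.0462). Zm00001d045462 was at 68.6 ± 13.4 CPM in wild type JA-untreated and at 15.4 ± 3.17, 18.5 ± 2.93 and 18.7 ± 9.19 CPM in the titled wild type JA-treated, titled mutant JA-untreated and mutant JA-treated groups (2.16 ± 0.42, edgeR adjusted p = 0.0301). Zm00001d029716 was highest in the titled wild type JA-treated group, at 40.6 ± 4.9 CPM against 8.3 ± 3.5 to 14.3 ± 7.17 CPM elsewhere (−2.91 ± 0.54, edgeR adjusted p = 0.0216). Zm00001d044130 was at 12.9 ± 0.096 and 11.2 ± 1.24 CPM in the 2 disagreeing groups and at 3.08 ± 1.38 and 6.66 ± 2.87 CPM in wild type JA-untreated and mutant JA-treated (−2.76 ± 0.54, edgeR adjusted p = 0.029). DESeq2 called 140 genes in this contrast, and 289 passed without the low-count filter. Wild type JA-untreated replicates 1 and 3, titled wild type JA-treated replicate 3, titled mutant JA-untreated replicates 2 and 3 and mutant JA-treated replicates 2 and 3, each left out, gave 25, 40, 47, 43, 46, 36 and 37, and 124 genes passed with ENSRNA features left out of the counts. The calls of Zm00001d006010, Zm00001d045462, Zm00001d029716 and Zm00001d044130 were lost in 10, 9, 5 and 10 of the 12 fits that left out 1 library, with edgeR adjusted p up to 0.14, 0.11, 0.072 and 0.09.

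The genes changed in the mutant of the genotype experiment were followed in the other experiments, which used separate libraries. Of 1104 such genes 888 were tested in the JA experiment. Their direction was the same for 73.5% in titled wild type JA-treated against wild type JA-untreated, for 67.1% in mutant JA-treated against wild type JA-untreated and for 65.8% in mutant JA-treated against titled mutant JA-untreated. It was the same for 56.6% in titled mutant JA-untreated against wild type JA-untreated and for 48.5% in mutant JA-treated against titled wild type JA-treated. Over all genes tested in both experiments the same shares were 57.3%, 55.9%, 55%, 52.3% and 49.1%. For IAA, where 757 of the 1104 genes were tested, the direction was the same for 53.2%, against 50.4% of all genes. Over the 888 features the Pearson correlations with the genotype experiment were 0.42, 0.16, 0.11, 0.09 and −0.31 in the same order, and with each library left out they ran from 0.35 to 0.54, 0.07 to 0.25, −0.02 to 0.27, −0.11 to 0.25 and −0.43 to −0.19. Over the 861 nuclear genes among them the Pearson correlations with the JA comparisons were 0.41, 0.38, 0.34, 0.11 and 0.01 in the same order, with Spearman correlations of 0.41, 0.36, 0.32, 0.15 and 0.01. When each library was left out in turn, the nuclear Pearson values ran from 0.36 to 0.54, 0.35 to 0.46, 0.30 to 0.48, −0.09 to 0.15 and −0.22 to 0.04. These correlations are across genes, which are not independent replicates.

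**Figure D4:**
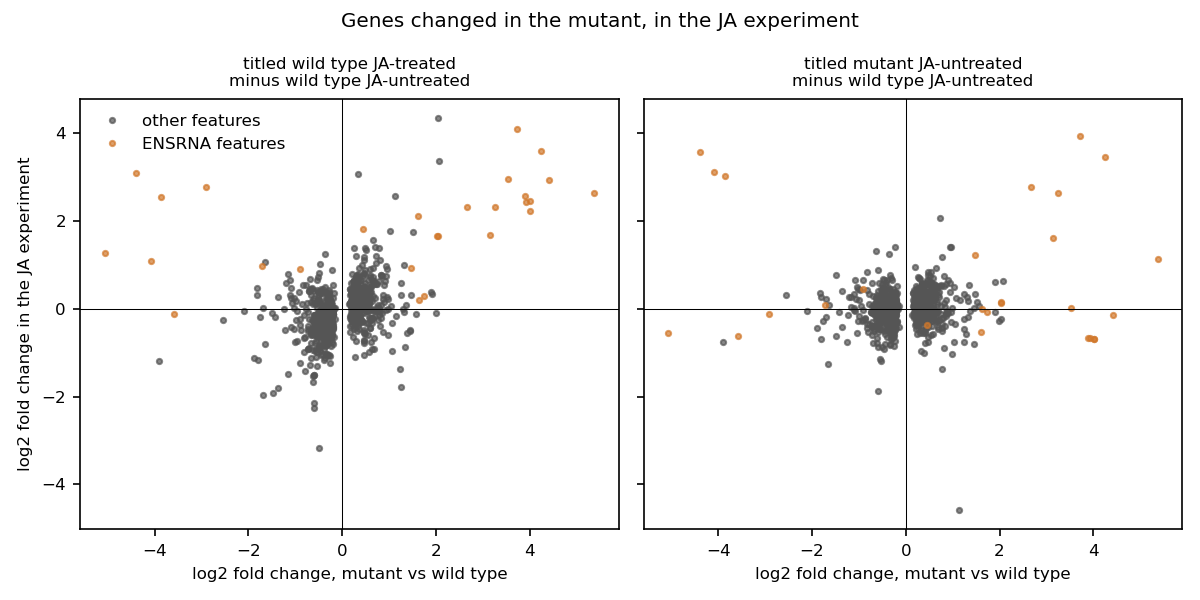
Log2 fold changes of the 888 features called in mutant against wild type (x axis) and their log2 fold changes in the JA experiment (y axis), 1 point per feature with ENSRNA features in orange; the left plot shows titled wild type JA-treated and the right plot titled mutant JA-untreated, each minus wild type JA-untreated. The direction is the same for 73.5% of the features on the left and 56.6% on the right.

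Called genes also overlapped across experiments. Between the genotype experiment and titled wild type JA-treated against wild type JA-untreated, 61 genes were higher in both and 45 lower in both, where independent lists would give 12 and 10.3, and 16 moved in opposite directions against 22.2. For mutant JA-treated against titled mutant JA-untreated, 41 were higher in both and 33 lower in both, with 5.5 and 7.1 from independent lists. For mutant JA-treated against titled wild type JA-treated, 31 moved in opposite directions against 14.9, with 22 higher in both and 14 lower in both against 8.6 and 6.4. For titled mutant JA-untreated against wild type JA-untreated, 29 were higher in both against 7.1, 10 lower in both against 4, and 16 moved in opposite directions against 10.9 (odds ratio 3). All 13 overlaps computed across experiments passed Fisher's exact test across genes, with adjusted p from 3.2e-29 to 0.011. The expected numbers take every tested gene as equally likely to be called. Genes were not matched for abundance, so an excess of shared calls alone does not show a shared response.

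Genes that responded to IAA also overlapped with other comparisons. With the mutant of the genotype experiment 23 were higher in both and 8 lower in both, against 5.1 and 3.9 from independent lists, and 13 moved in opposite directions against 8.9 (odds ratio 3.06, adjusted p = 1.7e-08, Fisher's exact test across genes). With titled mutant JA-untreated against wild type JA-untreated 29 genes were shared (odds ratio 7.01, adjusted p = 1.9e-13), of which 8 were higher in both against 1.6 from independent lists, 3 lower in both against 1.1, and 18 moved in opposite directions against 2.7. With titled wild type JA-treated against wild type JA-untreated 32 were shared, 5 higher in both against 2.5, 9 lower in both against 2.6, and 18 in opposite directions against 5.1. Shared genes thus exceeded independent lists in both directions, and the directions were not tested against each other. Here too the genes were not matched for abundance.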

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

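The tests of explanations below were chosen after the results were seen, except the test of exchanged titles. The non-additive contrast of genotype and JA stood out because it tests directly whether an effect differs between groups, a meaning it has only if the titles or their exchange are right, not if the genotype fields are. It passed for 71 genes, and the log2 contrasts of the nuclear genes it singled out were 2.16 for Zm00001d045462, 1.99 for Zm00001d006010, −2.91 for Zm00001d029716 and −2.76 for Zm00001d044130. Of 100 splits of the 12 libraries into groups of the same sizes, the real one included, 1 gave as many genes, and the highest of the others gave 33. The other splits mix 4 groups that differ in many genes, which raises the spread within the mixed groups and lowers their counts, so this test is void and chance stays open for the count of 71.

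For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. In each, 1 split gave as many genes, the real one. The other splits mix the groups compared, which raises the spread within them and lowers their counts, so they cannot serve as a measure of chance. The real and the highest other counts were 1104 and 1 for mutant against wild type, 186 and 6 for IAA, 1147 and 0 for mutant JA-treated against wild type JA-untreated, and 586 and 0 for titled wild type JA-treated against wild type JA-untreated. They were 328 and 0 for mutant JA-treated against titled mutant JA-untreated, 307 and 1 for titled mutant JA-untreated against wild type JA-untreated, and 413 and 2 for mutant JA-treated against titled wild type JA-treated.

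The disagreeing labels of 2 JA groups were weighed with the genes that changed in the mutant of the genotype experiment. The correlation with that experiment was higher by 0.33 for titled wild type JA-treated than for titled mutant JA-untreated, both against wild type JA-untreated, and the difference stayed above 0 in 15 of 15 fits that left out 1 library, which is consistent with exchanged genotype words in the 2 titles, the reading that the genotype fields give. By that difference exchanged whole titles, the reading in the names given to the deposited counts, cannot be told apart from exchanged genotype words. On both readings the group titled wild type JA-treated is mutant. The smallest difference in those fits was 0.22, and the part of the test that needed jasmonate genes had no named members. On the reading of the genotype and treatment fields the 2 disagreeing groups would repeat the 2 others, yet 113 genes changed in the same direction in both differences between groups that would then be alike, where independent lists would give 5.8, so that reading would need a batch between them. Exchanged whole titles would make both of those differences JA responses, and would need no such batch. If titles were right, titled mutant JA-untreated against wild type JA-untreated and mutant JA-treated against titled wild type JA-treated would show genotype alone. Their nuclear Pearson correlations with the genotype experiment were 0.11 (−0.09 to 0.15 with each library left out) and 0.01 (−0.22 to 0.04). Those of the JA responses by title were 0.41 (0.36 to 0.54) and 0.34 (0.30 to 0.48). These values argue against right titles for the 861 nuclear genes. Yet 29 genes were higher in both for the first, against 7.1 from independent lists. A JA response like the effect of the mutation was not tested.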

How the results depend on the processing

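The alternatives that leave out ENSRNA or organelle features were chosen after seeing the data. RLE scaling and library sizes without the 50 most abundant features moved no count of changed genes by over 1.5 times. DESeq2 called 560 genes for mutant against wild type and 140 in the non-additive contrast. Without the low-count filter 364 genes were called for IAA, 289 in the non-additive contrast and 475 for titled mutant JA-untreated against wild type JA-untreated. Its absence moved the share of higher genes by over 10 points, to 31.6% for IAA and to 40.2% for mutant JA-treated against wild type JA-untreated. It gave 52.4% for titled mutant JA-untreated against wild type JA-untreated and 42.6% for mutant JA-treated against titled wild type JA-treated. A minimum absolute log2 fold change of 1, which by construction only removes genes, left 174 for genotype, 74 for IAA, 462, 228 and 96 for mutant JA-treated, titled wild type JA-treated and titled mutant JA-untreated against wild type JA-untreated, 32 non-additive, and 107 and 150 for mutant JA-treated against titled mutant JA-untreated and titled wild type JA-treated. Fits of 6 libraries alone, with fewer libraries, gave 214 and 224 for the last pair. Exchanging the 2 groups swaps the comparisons by construction: 307 and 586 genes for titled wild type JA-treated and titled mutant JA-untreated against wild type JA-untreated. Leaving out ENSRNA features gave 319 for IAA and 124 non-additive, and leaving out organelle features too gave 325 and 133. Except where construction is named, the cause was not tested.

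With the replicate number as a block 47 genes passed in the non-additive contrast, and no other count over all genes moved by over 1.5 times. Among feature groups, ENSRNA features lower in mutant against wild type went from 8 to 16, those higher and lower after IAA from 1 and 10 to 6 and 17, and the mitochondrial call after IAA was lost. The numbers do not pair the samples: 1 of 21 pairs of deviations correlated over 0.1, with a range of −0.12 to 0.13. Leaving out each library gave 701 to 841 genes for genotype, 78 to 191 for IAA, 802 to 870 for mutant JA-treated against wild type JA-untreated, 25 to 57 non-additive, 300 to 439 for titled wild type JA-treated and 154 to 194 for titled mutant JA-untreated against wild type JA-untreated, and 180 to 216 and 242 to 297 for mutant JA-treated against titled mutant JA-untreated and titled wild type JA-treated.

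Of 846 recomputed values of named genes 684 kept direction and call, 159 lost the call and 3 reversed. The reversals came with exchanged groups: Zm00001d018819 at −1.29, Zm00001d034538 at 1.4 and orf147-b at −0.14. The correlation with the genotype experiment changed sign to −0.02 and −0.04 at the minimum log2 fold change for mutant JA-treated against wild type JA-untreated and titled mutant JA-untreated. It was −0.16 with DESeq2 for titled mutant JA-untreated against wild type JA-untreated, and −0.31 and 0.11 with exchanged groups for mutant JA-treated against titled mutant JA-untreated and titled wild type JA-treated. With each library left out, the correlation over all called features ran from −0.02 to 0.27 for mutant JA-treated against titled mutant JA-untreated and from −0.11 to 0.25 for titled mutant JA-untreated against wild type JA-untreated, so its sign is not settled in either. The minimum log2 fold change moved the share of higher genes to 64.9% for IAA and 66.7% for mutant JA-treated against titled wild type JA-treated. The IAA libraries, which were shallower and more variable, recovered 27% of simulated 2-fold changes, against 74% in the genotype libraries.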

Other observations

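The tests of explanations in this part were chosen after the results were seen. Among chloroplast genes, ndhA and ndhD, which encode subunits of the chloroplast NADH dehydrogenase-like complex, were the 2 with enough counts to be tested in the JA experiment. Both were higher in mutant JA-treated than in wild type JA-untreated endosperm (log2 fold changes 1.77 ± 0.46 and 1.77 ± 0.45 SE, edgeR adjusted p = 0.022 and 0.02), and DESeq2 called 0 of the 2, with 2 at an unadjusted p under 0.05. By edgeR 0 chloroplast protein-coding features were called there without wild type JA-untreated replicates 1 or 2 or mutant JA-treated replicates 1, 2 or 3, with 19, 19, 9, 19 and 19 at an unadjusted p under 0.05. Without wild type JA-untreated replicate 3, 19 of 19 were called higher, and 12 of 12 with ENSRNA features left out of the counts. Chloroplast features moved together, so these are not counts of independent genes. Without wild type JA-untreated replicates 1, 2 and 3, ndhA and ndhD both gave log2 fold changes of 1.63, 1.58 and 2.1. The estimated correlation among chloroplast protein-coding features was 0.67 in the genotype and 0.95 in the IAA experiment. In titled wild type JA-treated against wild type JA-untreated they were higher by 1.97 ± 0.42 and 1.84 ± 0.42 (edgeR adjusted p = 0.013 and 0.02), with 0 of the chloroplast protein-coding features tested called by edgeR without wild type JA-untreated replicates 1 or 2 or titled wild type JA-treated replicates 1 or 2, where 19, 19, 12 and 2 had an unadjusted p under 0.05. There too 19 of 19 were called higher without wild type JA-untreated replicate 3 or titled wild type JA-treated replicate 3, and 12 of 12 without ENSRNA features. The mitochondrial ccmFC, needed for cytochrome c maturation, was higher in mutant JA-treated endosperm by 1.17 ± 0.35 (edgeR adjusted p = 0.048), a call lost with DESeq2 (adjusted p = 0.18), with the replicate block and without each of the 6 libraries in turn (edgeR adjusted p up to 0.17). These 3 genes were chosen after their values were seen.

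Genes changed in the mutant of the genotype experiment were concentrated in a run of identifiers, Zm00001d040 to Zm00001d042, where 18.2% of 925 tested genes were called against 5.5% elsewhere. The run was set from these same calls. It was the longest stretch of adjoining bins of 1000 identifiers with at least 2 times the overall share of 6.1%. The bins on its sides, Zm00001d039 and Zm00001d043, had 8.2% and 11.2% and were counted as elsewhere, so the edges of the run follow from that threshold. The run holds Zm00001d041436, Zm00001d041300 and Zm00001d040153, named for that experiment. It also holds Zm00001d042140, Zm00001d042361 and Zm00001d042504, named in the JA experiment. Shuffling calls among genes of like abundance gave the fullest bin a p of 1e-04, the smallest that 10000 shuffles can give, which argues against abundance. The share was still 2.27 times that elsewhere after neighbouring calls were thinned, against reads shared between neighbours, and 53.6% of the called genes were lower, against a loss of mapped reads in the mutant line alone. Loss of mapped reads in both lines, at different genes, would move genes in both directions. That was not tested. For a genome segment that differs between the lines, the odds ratio of a call in the run was 1.5 in mutant JA-treated against wild type JA-untreated (adjusted p = 0.0051, Fisher's exact test across genes), and 1.02 and 1.07 (adjusted p = 0.89 each) in titled mutant JA-untreated against wild type JA-untreated and mutant JA-treated against titled wild type JA-treated, which by title differ in genotype alone. It was 1.51 and 2.3 (adjusted p = 0.04 and 0.00017, Fisher's exact test) in titled wild type JA-treated against wild type JA-untreated and mutant JA-treated against titled mutant JA-untreated. The excess was uneven over the run in mutant JA-treated against wild type JA-untreated and these comparisons. In that order 8.7%, 0.6% and 0.6% were called in Zm00001d040, the fullest bin of the genotype experiment at 18.4%. Zm00001d041 had 13.2%, 5.3% and 5.3%, Zm00001d042 had 18.9%, 12.6% and 10.5%, and the rest 10%, 4.8% and 2.8%. A segment stays open until the labels are settled, as does an effect of ZmICE1a, and that identifiers follow genome order is an assumption.

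The higher ENSRNA features in titled wild type JA-treated endosperm were weighed against 1 library with a high share. Without replicate 1 the number called higher was 20, and 22 without wild type JA-untreated replicate 1, so that 1 library was not the whole source. With ENSRNA features left out of the counts 99.4% of the nuclear genes called in titled wild type JA-treated against wild type JA-untreated kept their calls, so ENSRNA reads did not set most of those calls. That fit called 820 genes, however, of which 544 were among the 586 of the main fit. Leaving these features out thus added many further calls. A difference in RNA preparation and an effect of the treatment both stay open and were not tested.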
